A study of Livoneca redmanii with 3 samples.

How the data were processed

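RNA from whole Livoneca redmanii specimens was sequenced in 3 libraries, 1 each for control, low salinity and low temperature. Per the labels' protocols, animals were taken from tilapia hosts, total RNA was extracted with TRIzol, and libraries were made with an Ion Total RNA-Seq kit, with RNase III fragmentation and PCR, for the Ion Torrent S5 platform. The labels' protocols name no DNase step. A remark in the series' design text says that the samples have been replaced, without giving what differed. Per the submitters' processing notes, FastQC 0.11.9, fastp 0.23.2 and Salmon 1.10.2 were used. The assembler, the annotation tool and any genome build are not given in the sources used here. Feature names have the form of assembled contigs, and no genome coordinates were used. Gene names and descriptions are those in the deposited tables.

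The authors deposited estimated counts per assembled transcript, which in the file are whole numbers. Estimated counts from Salmon need not be whole, so rounding before deposit is assumed from the values. The deposited count table had 33093 rows for 31922 distinct transcripts. Here 1005 transcripts were listed more than once, with 1171 extra rows, 1 per annotated protein and always with the same counts, and each was used once. The second deposited table holds a normalized signal per gene, which the authors made as counts times 1 factor per library. Dividing by the factors 0.431, 0.850 and 2.49 gave whole numbers for 100% of values, within 0.01 counts. The factors equal the inverse of median-of-ratios size factors over the 5740 transcripts with a count in all 3 libraries. This deposited table held 26084 genes, each represented by the first listed of its transcripts and not by a sum, and it kept 45.0%, 45.8% and 40.8% of the counts of control, low salinity and low temperature. For 439 of its genes the transcript was listed more than once, and the value was the count times the number of listings.

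Per the file headers, the authors' 3 comparison tables hold a mean score (baseMean), a log2 fold change with its standard error, a test statistic score, and unadjusted and adjusted p-values. The deposited log2 fold changes, p-values and scores have the column names of DESeq2 results, and the model behind them is not given in the sources used here. The baseMean score in the deposited tables equalled, for 100% of rows and within a relative tolerance of 0.001, the mean of normalized values rounded to whole numbers and scaled again. It equalled the mean of the unrounded normalized values for 4.79% of rows.

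The main measure was the log2 ratio of CPM between 2 libraries, with TMM scaling in edgeR 4.0.16 (R 4.3.3) and a prior count of 0.5. TMM gave scaling factors of 1.73 for control, 1.29 for low salinity and 0.449 for low temperature. Transcripts entered with a mean count of at least 10 over the 3 libraries, which left 8563. With 1 library per condition no test was run and no p-value or standard error was computed. A transcript passed the size rule at an absolute log2 ratio of at least 1. Counts carry exact Poisson 95% intervals, ratios exact conditional binomial (Clopper-Pearson) 95% intervals and shares exact binomial intervals, all for counting error only, since amplified reads without molecular identifiers are not independent molecules. A fold against a library at 0 was computed with TMM scaling against a floor of 3 counts per library. That floor is 0.808, 1.63 and 2.40 CPM in control, low salinity and low temperature. Such a fold is a lower bound for counting error under TMM scaling only, and another scaling can make it smaller. The number past the rule from counting noise alone was simulated with 100 Poisson draws from pooled proportions. It averaged 389 for low salinity against control, 192 for low temperature against control and 630 for low salinity against low temperature.

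Before the data were examined, 26 gene lists were fixed by text in names and descriptions. They cover ion-transport ATPases, osmoregulatory transporters with carbonic anhydrases, osmolyte metabolism, heat shock proteins, cold response, antioxidants, detoxification, cuticle, moulting hormones, muscle, oxidative phosphorylation and mitochondrially encoded proteins. The others are glycolysis, ribosomal proteins, ribosomal RNA, translation factors, ubiquitin and proteasome, immunity, respiratory and storage proteins, egg and ovary, testis and sperm, digestion, the nervous system, the cell cycle with histones, fish host tissue and transposable elements. A list needed at least 5 tested transcripts. The moulting hormone list had 2, with 296 counts in low temperature and 0 in control and in low salinity. The mitochondrial list had 1, with 207 counts in low temperature and 0 in the other libraries. List medians were placed among 10000 random lists matched on mean count in 20 bins. In the low-salinity against control comparison, where most members were at 0 in both libraries, these placements are not reported. The wider class of mobile-element annotation, which adds ribonuclease H, integrase and similar text, was set after the data were seen.

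Named genes followed a rule fixed at the same time. For each comparison, up to 10 transcripts with the highest and 10 with the lowest log2 ratio were taken from those with a name or description and a mean count of at least 50. They had to pass the size rule with an interval excluding 2-fold, with 1 per name, and names saying uncharacterized or hypothetical were left out. For each list the 2 most abundant members and the 2 with the largest ratio at a mean count of at least 50 were added. The text prints a selection of the genes this rule names, and the others are not reported here. The SLC12A8, EFTUD1 and muscle members counted as lower than control were singled out after their values were seen.

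The computation was tested on simulated counts for 8563 transcripts per comparison with 200 changed ones, 50 per fold. For low temperature against control it recovered 48.0% of 2-fold changes and 100% of 4-fold, 8-fold and 16-fold changes. In the low-salinity against control simulation it recovered 32.0%, 56.0%, 54.0% and 58.0%. Between low salinity and low temperature it recovered 66.0%, 94.0%, 100% and 98.0%. Alternatives were other scalings (total counts, median of ratios with DESeq2 1.42.0, upper quartile), count filters, prior counts, thresholds and the authors' normalized values. Abundant features, or the members of the ribosomal RNA and mitochondrial lists, were also removed. The ribosomal RNA list matched protein transcripts, so its removal says nothing about ribosomal RNA itself. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.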

Results

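Whole specimens of Livoneca redmanii, a cymothoid isopod that lives as a parasite on fish, were profiled by RNA sequencing under 3 conditions. The control animals were kept at 35 PSU and 26 °C, the low-salinity animals were brought gradually down to 8 PSU, and the low-temperature animals were brought down to 10 °C. The labels used here give no temperature for the low-salinity animals and no salinity for the low-temperature animals. Each condition was represented by 1 library, so no difference below has a replicate check, and every interval covers counting error only. The count table held 31922 distinct assembled transcripts. The control library summed to 2142836 counts, the low-salinity library to 1434390 and the low-temperature library to 2782324. A count was recorded for 17444 transcripts in control, 14173 in low salinity and 21628 in low temperature. The comparisons cover the 8563 transcripts with a mean count of at least 10 over the 3 libraries, of which 3757 carried a protein annotation.

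The 3 libraries held different kinds of transcript. Transcripts annotated as reverse transcriptases, endonucleases, integrases, ribonuclease H and other proteins of mobile genetic elements took 48.2% of the control counts (exact binomial 95% interval 48.1% to 48.3%) and 54.8% of the low-salinity counts (54.7% to 54.9%). In the low-temperature library they took 4.61% (4.59% to 4.64%). Transcripts with any other annotation took 11.1% of counts in control, 10.5% in low salinity and 16.4% in low temperature, and unannotated transcripts took 40.7%, 34.6% and 79.0%. Of the 3057 tested transcripts whose annotation text matched no mobile-element term, 2385 were at 0 in control, 2474 at 0 in low salinity and 172 at 0 in low temperature. This class can still hold contigs of mobile elements. For example, TRINITY_DN7_c0_g1_i16 is in it, although another contig of its gene is described as an endonuclease-reverse transcriptase.

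**Figure D1:**
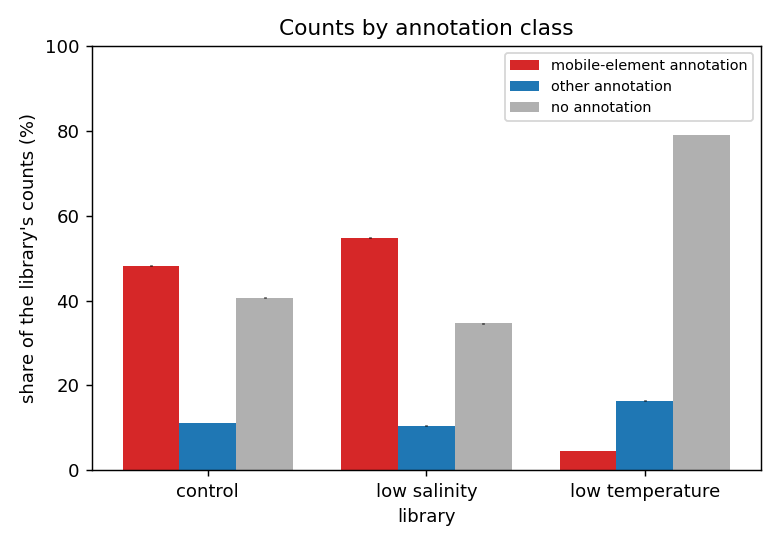
Share of each library's counts, in percent, taken by transcripts with mobile-element annotation, with other annotation and with no annotation; bars stand for 1 library each and error bars are exact binomial 95% intervals. Mobile-element annotation took 48.2% of counts in control and 54.8% in low salinity, against 4.61% in low temperature.

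The comparison of low temperature with control asked which transcripts differ between animals cooled to 10 °C and animals kept at 26 °C. Transcripts of the everyday machinery of the cell were abundant in the low-temperature library and at or near 0 in the control library. The beta-actin transcript ACTB (TRINITY_DN31_c0_g1_i20) had 6229 counts in low temperature (exact Poisson 95% interval 6075 to 6386) and 0 in control, at least 6174-fold higher against a floor of 3 counts per library with TMM scaling. Total counts and upper-quartile scaling shift this bound, and the other bounds against a control at 0, by -1.95 and -2.47 log2 units. All 120 tested transcripts of cytosolic ribosomal proteins were higher in low temperature, with 17990 counts there against 11 in control, and 111 of them were at 0 in control. Transcripts of mobile elements lay on the other side, with 314 of 421 lower in low temperature and 36 higher. In total 4244 of the 8563 tested transcripts were at least 2-fold higher in low temperature and 3678 were at least 2-fold lower. Of those higher, 3477 were at 0 in the control library. The mean-count filter fixed part of this, since 3260 tested transcripts had counts only in low temperature and entered only through them. Such transcripts are higher by construction, and they were 2265 of the 3057 whose annotation text matched no mobile-element term.

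**Figure D2:**
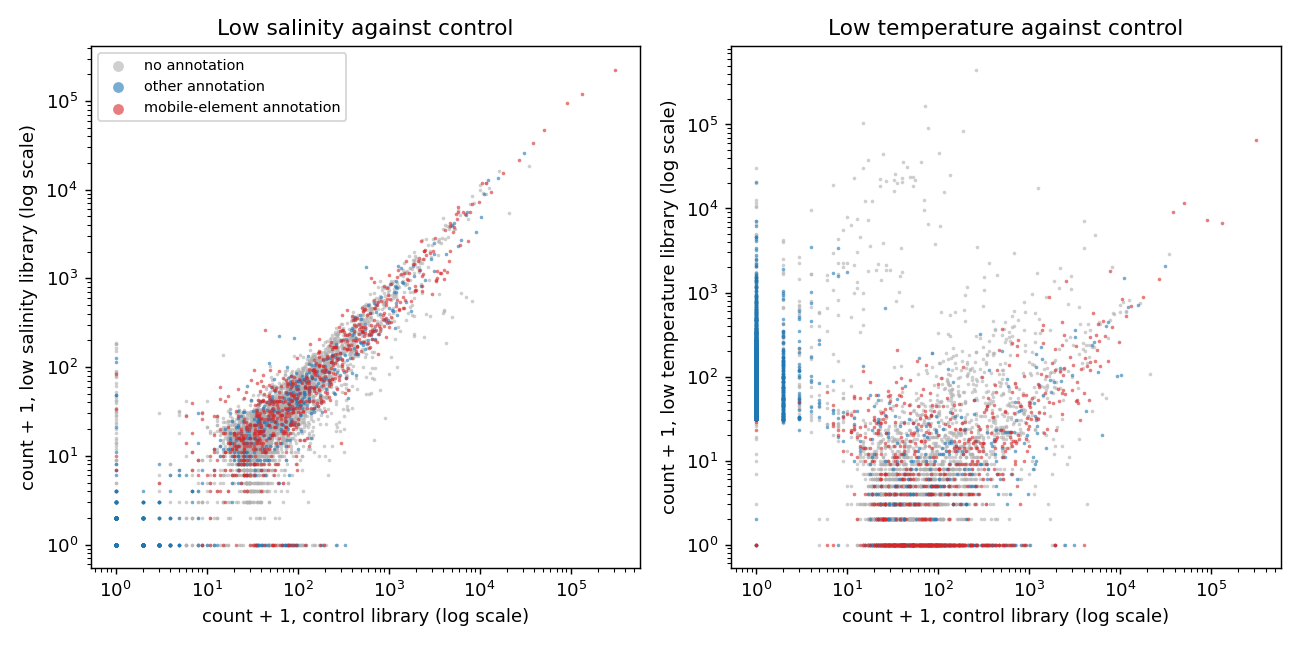
Count plus 1 of each of the 8563 tested transcripts, on log axes, in the low-salinity library (left) and the low-temperature library (right) against the control library; each point is 1 transcript, coloured by annotation class. The low-salinity counts follow the control counts, whereas in low temperature 3477 of the transcripts past the 2-fold rule lie at 0 in control.

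Named transcripts with the highest ratios of low temperature to control came from hemolymph, yolk, muscle and core metabolism, and each was at 0 in control. A transcript described as larval serum protein (TRINITY_DN12_c0_g1_i14), of the hemocyanin-like storage proteins of arthropod hemolymph, had 20734 counts in low temperature, the highest of this set. A second contig of the same assembled gene (TRINITY_DN12_c0_g1_i5), described as hemocyanin, had 4529. The yolk precursor vitellogenin, Vg (TRINITY_DN9_c0_g1_i1), had 4338 counts and was at least 4299-fold higher. The myosin heavy chain unc-54 (TRINITY_DN17_c0_g1_i8) had 3353, the actin ACTG1 (TRINITY_DN31_c0_g3_i1) 3163 and the fatty acid-binding protein FABP6 (TRINITY_DN30239_c0_g1_i1) 2476. GAPDH (TRINITY_DN19_c0_g1_i6), a glycolytic enzyme, had 2436 counts, and the translation elongation factor EF1a-F2 (TRINITY_DN56_c0_g1_i23) had 2062, at least 2414-fold and 2044-fold higher.

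Named transcripts with the lowest ratios were at 0 in low temperature and came mostly from mobile elements. A transcript described as K02A2.6-like (TRINITY_DN55_c0_g1_i2) had 4065 counts in control, at least 455.7-fold lower in low temperature, but the 17 contigs of its gene summed to 135 counts in low temperature and 9229 in control. A reverse transcriptase (TRINITY_DN15_c0_g1_i5) had 931 counts in control, a Tf2-type retrotransposable element (TRINITY_DN59_c0_g1_i8) 882 and a jockey-like mobile element (TRINITY_DN270_c0_g1_i7) 619. Other annotations in this set were BH2 domain binding (TRINITY_DN69_c0_g1_i7, 3169 counts in control), the WD40 region of the mRNA-decapping enhancer Ge1 (TRINITY_DN6_c0_g1_i7, 2480, with 972 and 22942 over its gene) and positive regulation of TOR signaling (TRINITY_DN7_c0_g1_i16, 1914). Another contig of that last gene (TRINITY_DN7_c0_g1_i1), with 0 counts in low temperature and 1934 in control, was also described as an endonuclease-reverse transcriptase.

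Gene lists for ion and water balance were almost absent from control, apart from 2 SLC12A8 transcripts. All 23 tested transcripts of ion-transport ATPases were higher in low temperature, with 2586 counts against 0. Among them ATP1B1 (TRINITY_DN178_c0_g1_i7), a beta subunit of the sodium pump, had 456 counts. Of 13 transcripts of osmoregulatory transporters and carbonic anhydrases, 11 were higher, including the cotransporter SLC12A1 (TRINITY_DN1927_c0_g1_i6) with 237 counts against 0 and the carbonic anhydrase Car15/CA6 (TRINITY_DN621_c0_g1_i1) with 167 against 0. The list summed to 1088 counts in low temperature and 151 in control. The 2 lower ones were both annotated SLC12A8 and were the only members with a count in control. The more abundant of these (TRINITY_DN1032_c0_g7_i1) had 4 counts in low temperature and 105 in control, 8.83-fold lower. All 10 tested transcripts of free amino acid and osmolyte metabolism were higher, with 596 counts against 0.

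Stress-related lists went the same way. In every list, members at 0 in both control and low salinity passed the mean-count filter only through low temperature, so they are higher by construction. All 79 transcripts of heat shock proteins and chaperones were higher in low temperature (12709 counts against 6), led by HSP90AA1 (TRINITY_DN80_c0_g1_i4) with 1561 counts and HSP90AB1 (TRINITY_DN80_c0_g1_i5) with 758, both against 0. The cold-response list of Y-box proteins, fatty acid desaturases and elongases had all 14 members higher. Of these, 12 were at 0 in control and all 14 in low salinity, so the direction of most was fixed by the filter. The list's most abundant member, YBX2 (TRINITY_DN203_c0_g1_i1), described only by a cold shock protein domain, had 693 counts against 0. All 23 antioxidant transcripts were higher, with GSTM3 (TRINITY_DN223_c0_g1_i2) at 416 counts against 1, a ratio of 1237 (exact 95% interval 220.8 to 48971), and GPX3 (TRINITY_DN28_c0_g1_i1) at 264 against 0. The detoxification list had all 40 higher, led by a sulfotransferase (TRINITY_DN53680_c0_g1_i3) with 325 counts against 0. The immune list had all 14 higher, and its most abundant member, a C-type lectin domain transcript (TRINITY_DN43_c0_g1_i7), had 3390 counts against 7, a ratio of 1440 (698.1 to 3584).

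The lists for tissue structure and energy metabolism were likewise higher in low temperature. Of 79 muscle transcripts, 78 were higher, and the 1 lower transcript also carried a ribonuclease H annotation. All 48 nuclear-encoded transcripts of oxidative phosphorylation were higher, including the ATP synthase subunits ATP5B (TRINITY_DN157_c0_g1_i1) with 1474 counts and ATP5A1 (TRINITY_DN301_c0_g1_i5) with 784, both against 0. All 26 glycolysis transcripts were higher, with the enolase enol-1 (TRINITY_DN137_c0_g1_i1) at 891 against 0. All 28 cuticle and chitin transcripts, all 68 of the ubiquitin and proteasome list and all 11 of the respiratory and storage protein list were higher. Translation factors had 87 of 92 higher. The 5 lower ones were EFTUD1 contigs, of which 4 also carried mobile-element annotation, such as TRINITY_DN182_c0_g1_i7 with 121 counts against 3751. RPL4 (TRINITY_DN122_c0_g1_i3), among the most abundant ribosomal protein transcripts, had 802 counts against 0.

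Lists for organs mostly had the same direction where their members were cellular genes. All 9 transcripts of the egg and ovary list were higher, with 13256 counts against 3, most of them vitellogenin. All 6 of the testis and sperm list were higher, but its most abundant member was the peptidase ACE (TRINITY_DN492_c0_g1_i15), at 714 against 0, which is not specific to sperm. All 5 of the nervous system list were higher, but its most abundant member was an actin annotated ACTB (TRINITY_DN65058_c0_g1_i1), at 171 against 0, which is not specific to nerve. Of 51 digestive enzyme transcripts, 36 were higher, such as a secreted trypsin-like protease (TRINITY_DN146_c0_g1_i29) with 757 against 0. The 14 lower ones, among them estA (TRINITY_DN8_c0_g1_i1) with 0 against 350, were all among the list members with mobile-element annotation. The fish host list had 21 of 23 higher and 2 lower, and neither of those 2 carried mobile-element annotation. Its most abundant members were immunoglobulin-domain transcripts, led by the muscle protein sls (TRINITY_DN628_c0_g1_i3), named after an insect gene, with 369 against 0. The ribosomal RNA list matched 23 protein transcripts whose descriptions mention ribosomal RNA, such as RPSA (TRINITY_DN714_c0_g1_i1), all higher in low temperature.

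The transposable element list had a median log2 ratio of -2.82. Its most abundant member, an endonuclease-reverse transcriptase (TRINITY_DN4_c0_g1_i2), had 64571 counts in low temperature and 309045 in control, 1.61-fold lower after scaling (log2 ratio -0.69), but its log2 ratio turned to 0.27 with median-of-ratios scaling. The cell cycle and histone list had 36 of 302 higher and 214 lower, but 280 of its members carried mobile-element annotation. Without these, 12 were higher and 10 lower.

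**Figure D3:**
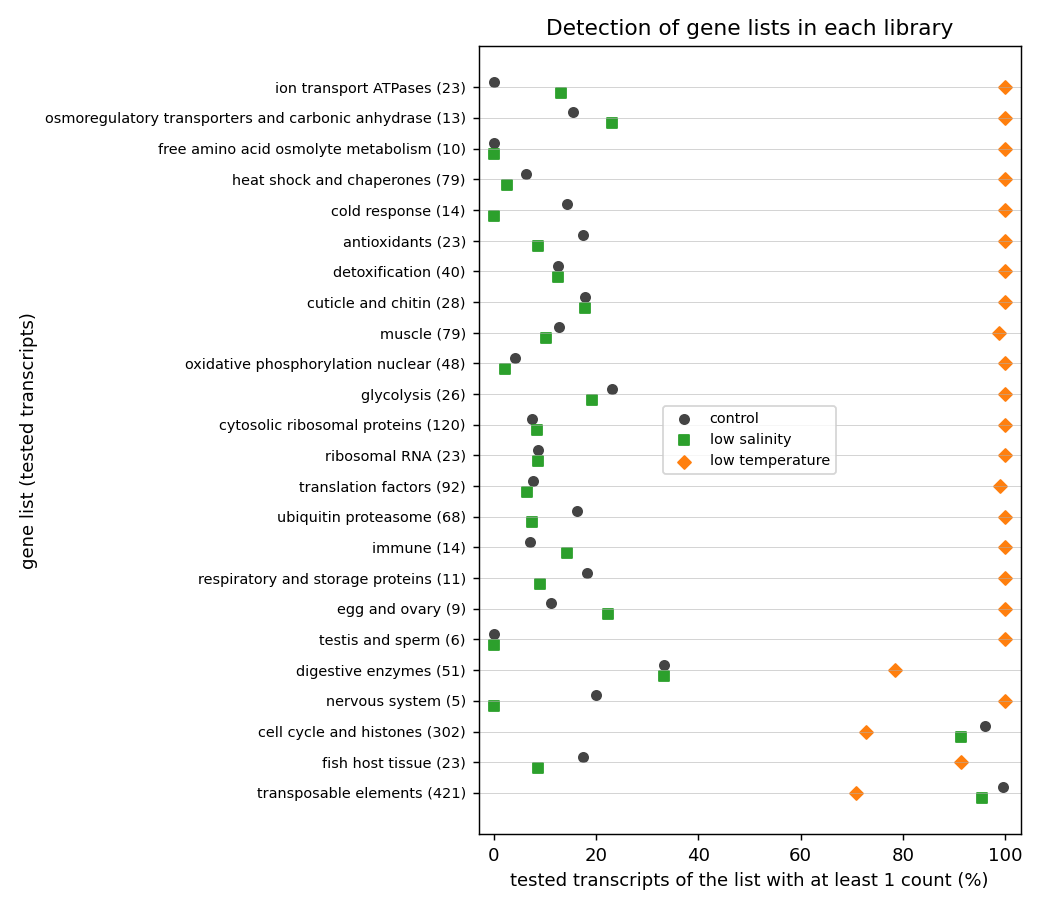
Percent of the tested transcripts of each gene list with at least 1 count in the control, low-salinity and low-temperature libraries; each point is 1 list in 1 library, and the number of tested transcripts stands in brackets. All 120 ribosomal protein transcripts were detected in low temperature, whereas 111 of them were at 0 in control. Transposable element transcripts were detected more widely in control and low salinity. Members at 0 in control and low salinity were tested only where low temperature had counts.

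The median log2 ratio of the ribosomal protein list was 8.43, or 6.67 with members at 0 set to 3 counts, and it was 7.18 when libraries were scaled by total counts. Over the 22 lists with a median above 1, the lowest median was 7.02, and the medians lay at or above the 86.6 percentile of random lists matched on mean count. The size of these medians follows in part from the mean-count filter. The random lists were matched on mean count and not on annotation class. Counts only in low temperature were found for 74.1% of tested transcripts with other annotation, 20.7% with none and 0% with mobile-element annotation. The percentiles therefore cannot separate the function of a list from the annotation class of its members. The choice of scaling moved all log2 ratios of this comparison by between -2.47 and 0.96, and 188 of the transcripts that were higher turned direction under another scaling. The share of higher transcripts among those past the rule was 53.6%, against 58.6% with median-of-ratios scaling and 41.7% with a mean count of at least 50. With the authors' normalized values, which hold 1 contig per gene, it was 84.0%.

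The comparison of low salinity with control asked which transcripts differ between animals brought to 8 PSU and animals at 35 PSU. Mobile-element and unannotated transcripts took most of the counts in both libraries. Of 8563 tested transcripts, 481 were at least 2-fold higher in low salinity and 1139 were at least 2-fold lower. With mobile-element annotation 63 were higher and 99 lower, with other annotation 153 and 254, and with none 265 and 786. Counting noise alone gave a mean of 389 transcripts past this rule in 100 simulated pairs, and 3792 of the tested transcripts had at most 3 counts in both libraries. Among transcripts with more than 3 counts in 1 of the 2 libraries, a restriction chosen after the data were seen, 302 were higher and 833 lower.

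Few transcripts of the ion and water balance lists had a count in either library. The 23 ion-transport ATPase transcripts summed to 3 counts in low salinity and 0 in control, and ATP1B1 (TRINITY_DN178_c0_g1_i7) was at 0 in both. The 10 transcripts of free amino acid and osmolyte metabolism were at 0 in both. Of the 13 osmoregulatory transporters and carbonic anhydrases, 10 were at 0 in low salinity and 11 in control. The transcript with the most counts, SLC12A8 (TRINITY_DN1032_c0_g7_i1), had 70 in low salinity and 105 in control, a scaled ratio of 1.34 (exact 95% interval 0.978 to 1.83) whose log2 value turned from 0.42 to -0.01 with total counts. The floor of 3 counts, the limit used here for a transcript at 0, is 0.000209% of the low-salinity counts and 0.00014% of the control counts.

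Other cellular lists were also near 0 in both libraries. Heat shock proteins and chaperones summed to 2 counts in low salinity and 6 in control over 79 transcripts, and HSP90AA1 was at 0 in both. Cytosolic ribosomal proteins summed to 13 and 11 over 120 transcripts, oxidative phosphorylation to 1 and 3 over 48, and glycolysis to 15 and 40 over 26. The cold-response list summed to 0 and 3, antioxidants to 7 and 11, detoxification to 5 and 6, cuticle and chitin to 6 and 6, and the ubiquitin and proteasome list to 5 and 11. Muscle summed to 25 and 48, the immune list to 4 and 7, and respiratory and storage proteins to 3 and 7. The egg and ovary list had 2 and 3, the testis and sperm list 0 and 0, the nervous system list 0 and 1, and the ribosomal RNA list 3 and 4. The fish host list summed to 45 and 156, of which an immunoglobulin-like transcript (TRINITY_DN69_c1_g1_i2) had 36 and 127, a ratio of 0.571 (0.383 to 0.832), whose log2 of -0.80 became -1.23 with total counts, past the size rule.

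Mobile-element transcripts were abundant in both libraries and went both ways. Of the 421 transcripts in the transposable element list, 38 were higher in low salinity and 59 lower, with a median log2 ratio of 0.06. Scaling by total counts gave 16 higher and 102 lower with a median of -0.36, and upper-quartile scaling gave 59 higher and 49 lower with a median of 0.27. The most abundant, the endonuclease-reverse transcriptase TRINITY_DN4_c0_g1_i2, had 225643 counts in low salinity and 309045 in control, a scaled ratio of 1.47 (1.46 to 1.48). A reverse transcriptase (TRINITY_DN1960_c0_g1_i11) had 95304 and 90934 counts, a ratio of 2.11 (2.09 to 2.13), but its log2 ratio of 1.08 became 0.65 with total counts, under the size rule. The cell cycle and histone list, in which most members are such contigs, had 32 higher and 44 lower of 302, against 13 and 77 with total counts and 44 and 40 with upper-quartile scaling. Digestive enzymes had 7 higher and 5 lower of 51. Here estA (TRINITY_DN8_c0_g1_i1), annotated both as a lipase and as a reverse transcriptase, had 435 and 350 counts, 2.50-fold higher (2.17 to 2.89), but its log2 ratio of 1.32 became 0.89 with total counts, under the size rule, and the ratio over its gene was 1.38 (1.29 to 1.47), and 1.02 with total counts. Translation factors had 1 higher and 3 lower of 92, against 1 and 7 with total counts, and their counts came almost entirely from EFTUD1 contigs, such as TRINITY_DN182_c0_g1_i7 with 1160 and 3751 counts, a ratio of 0.623 (0.582 to 0.665), whose log2 of -0.68 became -1.11 with total counts, past the size rule.

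Named transcripts at the extremes of this comparison included contigs of a single assembled gene that went opposite ways. Of the gene annotated with positive regulation of TOR signaling, TRINITY_DN128_c7_g1_i6 had 114 counts in low salinity and 0 in control, at least 76.5-fold higher, while TRINITY_DN128_c7_g1_i3 had 0 and 263, at least 43.5-fold lower. Summed over its 7 contigs the ratio was 0.865 (0.742 to 1.01), which became 0.642 with total counts and 1.00 with upper-quartile scaling. For BH2 domain binding, TRINITY_DN209_c0_g1_i15 had 111 and 48 counts and TRINITY_DN209_c0_g1_i30 had 0 and 334, with a ratio of 0.704 (0.617 to 0.800) over the gene. The nuclease activity contigs TRINITY_DN114_c0_g1_i18 (226 and 61) and TRINITY_DN114_c0_g1_i35 (0 and 85) also went opposite ways, with a ratio of 1.28 (1.17 to 1.40) over the gene that became 0.949 with total counts. So did the K02A2.6-like contigs TRINITY_DN258_c0_g1_i4 (65 and 35) and TRINITY_DN258_c0_g1_i3 (13 and 297), with 0.682 (0.626 to 0.743) over the gene.

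Among the remaining extremes, a reverse transcriptase (TRINITY_DN18_c0_g1_i42) had 262 counts in low salinity and 43 in control, 12.3-fold higher (8.86 to 17.4), but the ratio over the 44 contigs of its gene was 1.57 (1.55 to 1.59), and 1.16 with total counts. PDZPH1P (TRINITY_DN330_c1_g1_i8) had 1357 and 570, 4.79-fold higher (4.34 to 5.30), with 2.14 (2.05 to 2.24) over its gene that became 1.59 with total counts. The contig TRINITY_DN1128_c0_g1_i1, annotated NID2 and reverse transcriptase, had 0 and 192 counts, but its gene had 229 and 461, a ratio of 1.00 (0.850 to 1.17) that became 0.742 with total counts and 1.16 with upper-quartile scaling. A core histone transcript annotated HIST3H3/HIST1H3D (TRINITY_DN142_c0_g1_i8) had 15 and 138, a ratio of 0.219 (0.119 to 0.374), with 0.681 (0.604 to 0.766) over its gene, which was inside the size rule. The larval serum protein contig TRINITY_DN12_c0_g1_i14 had 7 counts against 0, beside its 20734 counts in low temperature, but its gene had 10 and 13, a ratio of 1.55 (0.608 to 3.82).

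Higher transcripts made up 29.7% of those past the rule. The share was 16.1% with scaling by total counts, 28.5% with median-of-ratios scaling and 42.0% with upper-quartile scaling. With the authors' normalized values it was 52.6%. Those values use median-of-ratios factors but hold 1 contig per gene, and the filter was applied to normalized values. They therefore differ from the main measure in more than scaling. The other scalings shifted the log2 ratio of library sizes by between -0.43 and 0.21. Transcripts at 0 in 1 library could move further, such as TRINITY_DN209_c0_g1_i30 from -8.68 to -9.37 with total counts. Requiring an interval that excludes no difference left 1018 transcripts, and summing contigs per assembled gene left 1029 genes.

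The comparison of low salinity with low temperature set the 2 stress libraries side by side. Cellular transcripts were at or near 0 in low salinity and abundant in low temperature, as they were for control. ACTB (TRINITY_DN31_c0_g1_i20) had 0 counts in low salinity and 6229 in low temperature, at least 3066-fold lower in low salinity with TMM scaling. Total counts and upper-quartile scaling shift bounds of this kind by 1.52 and 2.68 log2 units, toward smaller folds. The trypsin-family protease zetaTry (TRINITY_DN90_c0_g1_i7) had 0 and 1749 counts, at least 860.9-fold lower. The K02A2.6-like contig TRINITY_DN55_c0_g1_i2 had 1248 and 0, at least 281.7-fold higher, with 3096 and 135 over its gene. Of the 8563 tested transcripts, 3577 were at least 2-fold higher in low salinity and 4273 at least 2-fold lower, and 3643 of those lower were at 0 in low salinity. Among these, the 3260 with counts only in low temperature are lower by construction of the mean-count filter.

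The named transcripts lower in low salinity were again hemolymph, yolk, muscle and metabolic transcripts at 0 there. They included larval serum protein (TRINITY_DN12_c0_g1_i15, 7039 counts in low temperature), unc-54 (TRINITY_DN17_c0_g1_i8, 3353), ACTG1 (TRINITY_DN31_c0_g3_i1, 3163), FABP6 (TRINITY_DN30239_c0_g1_i1, 2476), GAPDH (TRINITY_DN19_c0_g1_i6, 2436), Vg (TRINITY_DN9_c0_g1_i7, 2069) and EF1a-F2 (TRINITY_DN56_c0_g1_i23, 2062). The higher ones were at 0 in low temperature. They included BH2 domain binding (TRINITY_DN69_c0_g1_i7, 1220 counts in low salinity), positive regulation of TOR signaling (TRINITY_DN7_c0_g1_i16, 1055, of a gene with another contig also described as an endonuclease-reverse transcriptase), the Ge1 WD40 region (TRINITY_DN6_c0_g1_i7, 963) and a Tf2-type element (TRINITY_DN59_c0_g1_i8, 292).

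By list, all 120 ribosomal protein, 79 heat shock and chaperone, 48 oxidative phosphorylation, 26 glycolysis, 68 ubiquitin and proteasome, 23 ion-transport ATPase and 10 osmolyte transcripts were lower in low salinity. So were all 14 cold-response, 23 antioxidant, 40 detoxification, 28 cuticle, 14 immune, 11 respiratory and storage, 9 egg and ovary, 6 testis and 5 nervous system transcripts, together with the 23 of the ribosomal RNA list. Muscle had 78 of 79 lower, translation factors 87 of 92, the osmoregulatory list 11 of 13, digestive enzymes 36 of 51 and the fish host list 21 of 23. Transposable elements had 306 of 421 higher and 41 lower, and the cell cycle and histone list 208 of 302 higher and 44 lower, but 8 higher and 12 lower without its 280 members with mobile-element annotation. SLC12A8 (TRINITY_DN1032_c0_g7_i1) had 70 counts against 4, a ratio of 11.9 (4.43 to 44.7). Higher transcripts made up 45.6% of those past the rule, against 40.4% with median-of-ratios scaling and 58.1% with a mean count of at least 50. With the authors' normalized values, which hold 1 contig per gene, they made up 16.3%. Other scalings moved all log2 ratios by between -0.99 and 2.68, and 186 of the transcripts lower in low salinity turned direction under one of them.

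Low salinity and low temperature were both set against the same control library. Across the 8563 transcripts their log2 ratios had a Pearson correlation of 0.180 and a Spearman correlation of 0.161. In 100 simulations of unchanged libraries against 1 control the means were 0.469 and 0.442. The simulated libraries shared 1 pooled profile, whereas in the data 3260 tested transcripts had counts only in low temperature. The simulated means therefore cannot say whether the responses are shared. Over the 4771 transcripts with more than 3 counts in control or low salinity, a filter chosen after the data were seen, the observed correlations were 0.191 and 0.256. Transcripts are not independent replicates, and these values describe the 3 libraries. The covariance was 1.28 against a simulated 0.0899. In both comparisons 273 transcripts were higher and 624 lower. Independent lists of the same sizes drawn from all 8563 transcripts would share 238 and 489, and unchanged libraries shared 49.5 and 16.2. But 3485 tested transcripts were at 0 in control and could not be lower than control. A further limit is that 3260 had counts only in low temperature and could not be higher in low salinity. These reference numbers therefore show neither an excess nor a deficit. The control cannot be split, so part of any overlap may come from the shared control.

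The authors' deposited table for low temperature against control listed 20659 transcripts at an adjusted p under 0.05, 14553 of them higher, over 26084 rows. The authors' deposited table for low salinity against control listed 711, of which 383 were higher. The authors' deposited table for low salinity against low temperature listed 20447, of which 5803 were higher in low salinity. With a 2-fold rule added, these authors' deposited tables held 20516, 448 and 20295 transcripts. In the authors' deposited tables, 16174 of the 20659 calls for low temperature and 180 of the 711 for low salinity had a mean count under 10. The direction was the same as that of the recomputed log2 ratio for 100% of the 2-fold calls for low salinity against control and for 99.985% of those for low temperature in the authors' deposited tables. Both come from the same libraries, so the shared direction is no independent check of the calls. Each condition had 1 library, so the standard errors in the authors' deposited tables, as small as 0.00258 on the log2 scale for low salinity against control, hold no replicate spread.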

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

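Alternatives that sum contigs per assembled gene, keep transcripts above 3 counts, leave out mobile-element annotation or use 2 libraries, and gene lists and gene sums under further scalings, were chosen after the data were seen; the others were planned. No paired analysis was possible because each condition has 1 library, and for the same reason no library could be left out within a group. For low salinity against control the count of 1620 became 9816 with no filter, 461 at a mean count of at least 50, 474 at an absolute log2 ratio of at least 2, 1018 with an interval excluding no difference, 626 with the authors' normalized values and 1029 per assembled gene. For low temperature against control 7922 became 29129 with no filter, 2192 at a mean count of at least 50 and 5149 per assembled gene. Between the 2 stress libraries 7850 became 27259, 2201 and 5122 in the same order. Fewer or more features enter under these filters by construction, and for the authors' values the cause was not tested. All other alternatives stayed within 1.5 times, between 1082 and 2077 for low salinity against control. Lower transcripts outnumbered higher ones for low salinity against control under every alternative except the authors' normalized values, with 329 higher and 297 lower. For low temperature against control, higher transcripts outnumbered lower ones except with total counts (4025 and 4292), upper-quartile scaling (3999 and 4394) and a mean count of at least 50 (913 and 1279). Between the 2 stress libraries, lower ones outnumbered higher ones except with total counts (4103 and 4099), upper-quartile scaling (4325 and 4009) and a mean count of at least 50 (1279 and 922).

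Lists with a median past the size rule numbered 24 for low temperature against control and for low salinity against low temperature, and 15 in each at a mean count of at least 50, where fewer lists keep 5 members. There the digestive enzyme median turned from 7.36 to -1.86 and from -7.30 to 2.13, where lipase contigs with mobile-element text, such as estA, outnumber the other members left; the cause was not tested. No list passed for low salinity against control under any list alternative. The correlation of 0.180 between the responses became 0.0633 at a mean count of at least 50 and 0.310 with total counts; the cause was not tested. Among named genes, enol-1 (TRINITY_DN137_c0_g1_i1), at 2 counts against 0 in low salinity against control, turned to -0.86 when features of that name were summed. For low salinity against control, 3792 transcripts were at or under 3 counts in both libraries, and no fold can be read for these.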

Other observations

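A handful of unannotated assembled genes made up much of the low-temperature library and were chosen here after their values were seen. TRINITY_DN5_c0_g1 took 24.8% of the low-temperature counts, TRINITY_DN0_c0_g2 took 9.09% and TRINITY_DN219_c0_g1 took 7.38%. In control they took 0.0275%, 0.0122% and 0.00653%, and in low salinity 0.00356%, 0.00363% and 0.000906%. The unannotated gene TRINITY_DN3_c0_g1, with 25 contigs, had 60462 counts in control, 5894 in low salinity and 20781 in low temperature, and it was 5.09-fold lower in low salinity than in control (exact 95% interval of the ratio 0.191 to 0.202). All 23 of its tested contigs were at least 2-fold lower in low salinity, with a median log2 ratio of -2.49.

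Core histone transcripts divided by assembled gene. Over 18 tested transcripts the sums were 2274 counts in control, 788 in low salinity and 488 in low temperature. Of these, 11 were higher in control and came from 3 of 8 assembled genes, while the other 7 were higher in low temperature. Best-matching proteins from cichlid fishes, the family of the tilapia host, held 0.990% of the annotated counts in control, 0.505% in low salinity and 1.52% in low temperature, by a list of 4 species written after the data were seen. Over 15 listed ray-finned fishes the shares were 3.89%, 2.71% and 5.36%. Annotated transcripts took 59.3%, 65.4% and 21.0% of all counts, so the order of these shares depends on the denominator. In the same order, cichlid matches had 12583, 4737 and 8916 counts, and ray-finned matches 49402, 25409 and 31369. Of all counts, both groups took a larger part in control than in low temperature. Contigs with mobile-element annotation were not left out, so these shares do not measure host material.

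Cellular transcripts were near 0 in the control and low-salinity libraries, and the histone and low-temperature tests below were chosen only after the result was seen. Over 525 transcripts of 8 cellular lists, those libraries together held 139 counts against 89987 in low temperature (0.154%). A lower share of messenger RNA in those libraries predicts 1 ratio at every abundance, but the ratio at 30 to 99 low-temperature counts was at least 10.2 times that at 1000 or more. That bound rests on 9 transcripts with 0 counts, and without that tier the ratio was 2.16, under the threshold of 3. Spearman's rho was -0.0043, against 0.320 to 0.455 for low-temperature counts thinned to the same sum. The thinned range assumes the low-temperature profile in every library, and 455 of the 525 transcripts were at 0 in both other libraries. For these 525 transcripts, the tiers and rho argue against lower messenger RNA yield with the low-temperature profile unchanged. With a different profile, lower messenger RNA yield stays open. Genomic DNA reads in those libraries had predicted a rho this low, but the thinned range rests on that profile, so rho does not decide for them. Nor is that hypothesis decided by the 61.1% of histone transcripts (37.5% of histone genes) that were higher in control. A response to low temperature cannot be told apart from a library difference, since each condition has 1 library.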
